A study of Homo sapiens with 6 samples.

How the data were processed

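Gene expression was measured by RNA sequencing in HCT116, a human colon carcinoma cell line, grown as 3 stable lines. One line carried a control, one over-expressed the wild type transcription factor TEAD4, and one over-expressed its mutant K178R, in the usual notation an arginine in place of a lysine. Each line had 2 libraries, made from total RNA with a TruSeq RNA kit, per the labels' protocols. Libraries were grouped by their titles. For 1 wild type library, replicate 2, the genotype field of the labels names TEAD5 rather than TEAD4. Its title names wild type TEAD4, so it stayed in that group. Nothing in the labels says that the libraries of a line came from separate cultures or separately made lines, so p-values measure only the spread between these libraries, which may be technical.

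The authors deposited 1 table per library with FPKM values, fragments scaled by transcript length and library size, for 20030 gene rows. The submitters' processing notes name the aligner Bowtie 0.12.2 and the genome build hg18. The program that computed FPKM, its annotation, its treatment of reads that match several genes and its use of strand are not given in the sources used here. The files list gene symbols that entered gene catalogues long after that build, so the annotation behind the values may not be the one the notes name, and no coordinates are taken from the files. The 4 rows whose identifier occurs more than once were left out, all of them among 27 rows whose identifiers had been turned into dates. Of the 20026 rows kept, 4066 were listed at 0 in every library.

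Depth was examined from the values themselves. The total of all FPKM values ranged from 283195 to 305329 per library. The number of reads is unknown. The relative value of 1 read was taken as the most common ratio to control replicate 1, among genes above 0 and under 0.1 FPKM in both libraries. It gave depths relative to control replicate 1 of 1.05 for the other control library, 0.933 and 0.920 for the wild type libraries, and 0.997 and 0.963 for the K178R libraries. The spread of replicate pairs was compared with counting noise over genes with 1 coding transcript of more than 600 bases. The spread beyond counting noise was 0% in the control pair (95% bootstrap interval 0% to 1.42%, 500 draws), 1.82% in the wild type pair (0.976% to 2.32%) and 1.57% in the K178R pair (0.753% to 2.40%). The same measure between groups was 9.15% for control and wild type, 5.13% for control and K178R, and 7.93% for wild type and K178R. Between the control libraries no spread beyond counting noise was thus found, though the interval overlaps those of the other pairs. The measure rests on medians and does not show single genes that differ, such as U2AF1 (19.6 and 5.71 FPKM). The control libraries were kept as 2 libraries, and each count was also computed with them averaged as 1 sample. Pearson's r of log2 FPKM across 9952 genes above 1 FPKM in all libraries was 0.998 within each group and 0.985 to 0.990 between groups, and genes are not independent replicates.

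FPKM values are not counts, so no count model was used. Genes with at least 0.5 FPKM in at least 2 libraries were tested, 11445 in all, a filter chosen once the unit of the files was known and before any test. The values were transformed to log2(FPKM + 1), and all log2 changes and thresholds are on that scale, which understates the change of genes with low values. Ratios of mean FPKM are named as such. limma 3.58.1 in R 4.3.3 was fitted with trend to all 6 libraries, with the means of the 3 groups as coefficients, no other covariate and no added scaling. All 3 contrasts were tested two-sided, with Benjamini-Hochberg adjustment over the genes of each and a threshold of 0.05. This is the form of test set for FPKM before the data were examined, when counts were also foreseen. The groups share 1 estimate of the spread because each has 2 libraries.

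Gene lists, 22 in all with 529 tested genes and none in more than 1 list, were fixed at the same time. For each, members called higher and lower were counted over all genes tested and adjusted over the list alone. camera from limma compared each list with the other genes, with a preset correlation of 0.01 and adjustment over the 22 lists of a contrast. camera with a correlation estimated from the data and fry were run beside it. fry does not compare a list with other genes, so a shift of all genes moves it too. In each comparison it also passed for lists that camera did not. Of the 66 set tests, 25 passed the threshold with the preset correlation and 0 with the estimated one. Each call is given with both adjusted p-values. With an estimated correlation camera has only the 3 residual degrees of freedom of the fit, so few lists can pass. For the p53 list, K178R against wild type, the camera adjusted p went from 7.4e-14 to 0.0707. Its estimated correlation, -0.0019, was below the preset one. For that list, not passing therefore does not show that correlation between genes removes the set result. In some other lists the estimated correlation was above the preset one. It was 0.156 for DNA replication, 0.0857 for cholesterol synthesis, 0.0738 for AP-1 and 0.0722 for ribosomal protein genes. For these, correlation and the few degrees of freedom cannot be told apart as the reason for not passing. The overlap of both comparisons against the shared control libraries was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

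The genes named were set by a rule written before the data were examined. They are the TEAD genes, YAP1, WWTR1, CTGF, CYR61 and ANKRD1, and per comparison the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 FPKM and no overlap between the libraries of both groups. Symbols starting with LOC, MIR, SNORA or SNORD were left out. Up to 4 called members of each list with the largest change were added (up to 2 with the lowest p where none was called), and up to 5 genes called in all 3 comparisons.

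The fit was tested on simulated data, 5 sets of 11445 genes with 200 changed genes each, drawn from the means and spread of these libraries for wild type against control. It recovered 74.0% of 1.25-fold changes, 89.0% of 1.5-fold changes and 96.7% of 2-fold changes, and 4.82% of calls were false. The simulated noise was normal and depended only on the mean of a gene. In the real comparison 5711 genes were called, so these rates need not hold there.

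Alternatives set before the data were examined were median-of-ratios and upper-quartile scaling, no filter and a stricter filter, pseudocounts of 0.1 and 0.5, only the libraries compared, the replicate number as a block, a threshold of 1 on the log2 scale, and leaving out each library in turn. Alternatives for counts alone were not run. Chosen after the data were seen were a threshold of 1.5-fold, the averaged control libraries, each line against a control library of its own, and the removal of a trend on GC content and length. That trend used the longest coding transcript of each gene in GENCODE release 29, found for 11328 of the tested genes (99.0%). Genes with near-identical copies, such as U2AF1, BOLA2, histone genes and keratin-associated protein genes, are uncertain because the treatment of reads that match several genes is unknown. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used to read the files.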

Results

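RNA of 3 stable HCT116 lines was compared, a control line, a line over-expressing wild type TEAD4 and a line over-expressing TEAD4 K178R, with 2 libraries each. TEAD4 is a DNA-binding transcription factor of the TEAD family, through which the Hippo pathway coactivators YAP1 and TAZ (gene WWTR1) reach DNA. The design asks what wild type TEAD4 and its mutant each change in the transcriptome. Values are FPKM, given as mean ± SD with n = 2 libraries per group. Relative depths lay between 0.920 and 1.05 of that of control replicate 1, and the number of reads is unknown.

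TEAD4 itself was measured first. The gene lies on the plus strand of chromosome 12 from 2959330 to 3040673 in GRCh38 (GENCODE release 29). TEAD4 stood at 17.1 ± 0.666 FPKM in the control line, 85.4 ± 1.37 in the wild type line and 71.8 ± 0.745 in the K178R line. The ratio of mean FPKM to control was 5.01 with wild type TEAD4 and 4.21 with K178R. On the log2(FPKM + 1) scale TEAD4 rose in both lines (log2 2.26, SE 0.03, adjusted p = 2.1e-07 and log2 2.01, SE 0.03, adjusted p = 2.1e-07). The K178R line held less TEAD4 RNA than the wild type line (log2 -0.25, SE 0.03, adjusted p = 0.00131). These values do not separate introduced from endogenous TEAD4. The wild type library with TEAD5 in its genotype field, replicate 2, read 84.4 FPKM of TEAD4 against 86.4 in replicate 1.

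Among the other TEAD genes, TEAD1 fell in both lines, from 18.6 ± 0.196 FPKM to 11.6 ± 0.133 with wild type TEAD4 and 10.6 ± 0.529 with K178R (log2 -0.64 and -0.75). TEAD2 was not called in any comparison (6.32, 6.29 and 6.56 FPKM in control, wild type and K178R). TEAD3 stood at 7.24, 8.14 and 6.42 FPKM, and was lower in K178R than in wild type (log2 -0.30, adjusted p = 0.00319). WWTR1 fell from 5.84 ± 0.00548 FPKM to 4.43 ± 0.0622 with wild type TEAD4 and 3.48 ± 0.0892 with K178R, and was lower in K178R than in wild type (log2 -0.28, adjusted p = 0.0031). YAP1 was at 25.03 FPKM in control, 28.3 in wild type and 23.1 in K178R, and lower in K178R than in wild type (log2 -0.28, adjusted p = 8.4e-04). Against control, the calls of YAP1 (log2 0.17, adjusted p = 0.00545) and TEAD3 (log2 0.15, adjusted p = 0.0439) in the wild type line ended under median-of-ratios scaling, with adjusted p = 0.11 and 0.34. YAP1 in K178R, not called in the main test (log2 -0.11, adjusted p = 0.0528), passed under that scaling (adjusted p = 0.0442) and did not after upper-quartile scaling (adjusted p = 0.0636).

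With wild type TEAD4, 4309 genes were higher and 1402 lower than in control. The largest rises included FHL1, a LIM domain protein, from 1.65 ± 0.0537 to 11.5 ± 0.278 FPKM (log2 2.24, SE 0.04, adjusted p = 2.4e-07). BAMBI, a pseudoreceptor that dampens TGF-beta signalling, went from 5.68 ± 0.329 to 29.5 ± 2.37 FPKM (log2 2.19, SE 0.06, adjusted p = 1.6e-06). The EGF receptor ligand EPGN went from 0.101 ± 0.0318 to 4.39 ± 0.0919 FPKM, the basement membrane collagen COL4A5 from 1.64 ± 0.00221 to 7.03 ± 0.0669, and the immunoproteasome subunit PSMB9 from 0.694 ± 0.345 to 4.48 ± 0.388. SYTL2 (log2 2.04) and the glutaredoxin GLRX (log2 1.70) rose as well, as did the keratin-associated protein genes KRTAP3-1 (log2 2.93) and KRTAP2-3 (log2 2.02), whose reads may be shared within their family. The largest well measured fall was that of the secreted growth factor BMP4, from 79.4 ± 0.193 to 10.3 ± 0.944 FPKM (log2 -2.84, SE 0.07, adjusted p = 1.2e-06). CAV1, the main coat protein of caveolae, fell from 127 ± 3.48 to 33.9 ± 2.34 FPKM, ANXA3 from 104 ± 1.16 to 21.4 ± 1.02, and KRT7 from 11.8 ± 0.254 to 2.88 ± 0.233. KRT13 (log2 -1.85), the efflux transporter ABCC2 (log2 -1.63), the troponin gene TNNC1 (log2 -1.49), MTUS1 (log2 -1.47) and PKIB, a protein kinase A inhibitor (log2 -1.39), also fell. U2AF1 had the largest fall (log2 -2.94) and is uncertain, since its control libraries read 19.6 and 5.71 FPKM and it has a near-identical copy, U2AF1L5. The split of calls depended on scaling, with 2865 higher and 2498 lower after median-of-ratios scaling, and 3185 and 2162 after upper-quartile scaling, and the median of all genes was 0.09 on the log2 scale. At an absolute log2 change of at least 1, 67 genes were higher and 22 lower.

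**Figure D1:**
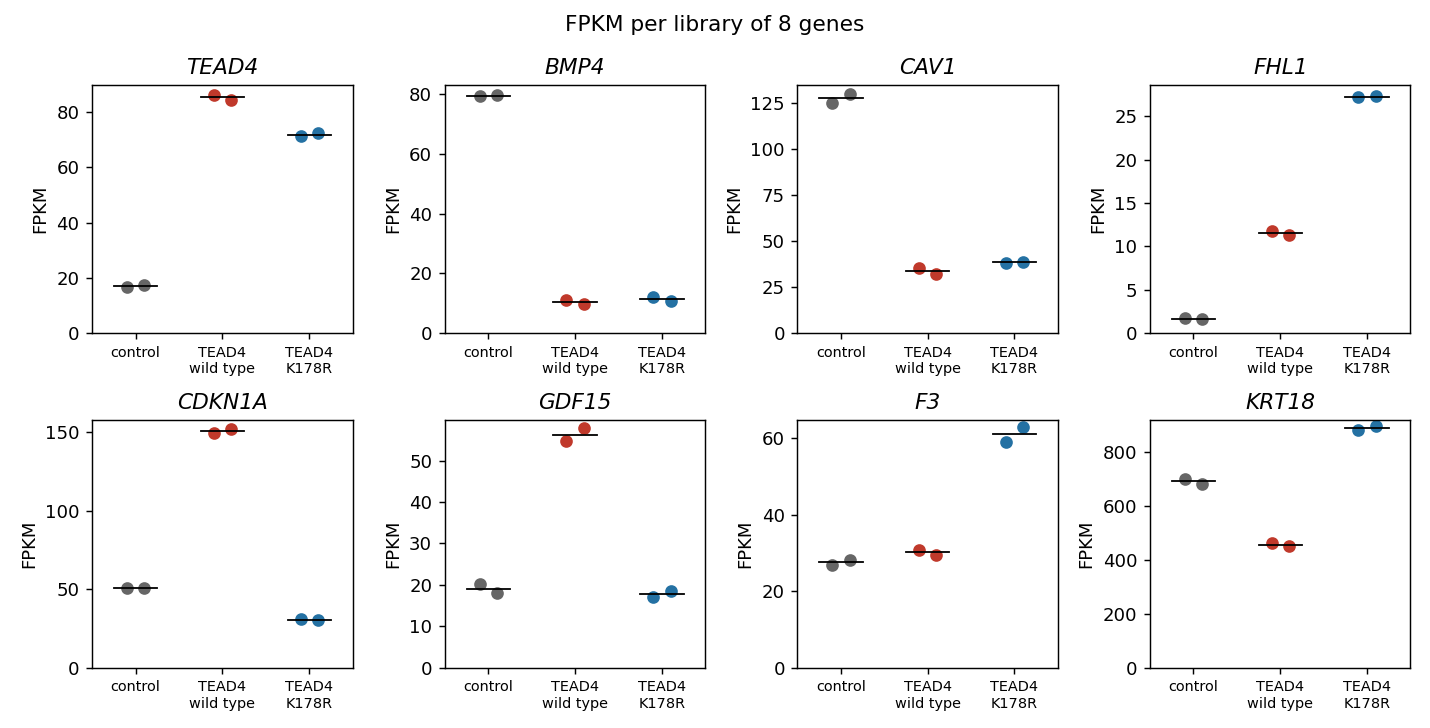
FPKM of 8 genes in each library, with dots for the 2 libraries of each line and a line for their mean, on linear axes from 0. TEAD4, FHL1, BMP4 and CAV1 moved the same way in both TEAD4 lines, while CDKN1A was at 50.9 FPKM in control, 151 in wild type and 30.7 in K178R.

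Target genes of p53, the tumour suppressor that is wild type in HCT116, rose with wild type TEAD4. Of 25 tested members, 23 were higher and 1 lower (24 and 1 adjusted over the list alone; camera adjusted p = 5.3e-08, and adjusted p = 0.116 with an estimated correlation). The cell cycle inhibitor CDKN1A went from 50.9 ± 0.200 to 151 ± 1.91 FPKM (log2 1.55, SE 0.03, adjusted p = 2.1e-07) and the cytokine GDF15 from 19.1 ± 1.55 to 56.3 ± 2.18 (log2 1.51). TP53INP1 (log2 1.34) and the death receptor FAS (log2 1.05) rose too, and the polo-like kinase PLK2 was the member that fell (log2 -0.59). In the NF-kB and inflammatory list, 15 of 16 were higher and 0 lower, and the same 15 adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.116 with an estimated correlation). Its largest changes were RELB (log2 1.43), CXCL1 (log2 1.30), BIRC3 (log2 1.21) and NFKB2 (log2 1.12). Of 28 interferon response genes, 21 were higher and 2 lower (22 and 2 adjusted over the list alone; camera adjusted p = 8.5e-04, and adjusted p = 0.118 with an estimated correlation). They were led by PSMB9 (log2 1.71) and the peptide transporter TAP1 (log2 0.95), which serve antigen presentation, with IFIT1 (log2 0.78) and IFI6 (log2 0.75). The 2 lower interferon genes became 1 without control replicate 1.

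Genes of DNA replication fell with wild type TEAD4. Of 32 tested, 24 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 1.1e-13, and adjusted p = 0.124 with an estimated correlation). The helicase subunit MCM5 went from 64.2 ± 1.24 to 42.6 ± 1.24 FPKM (log2 -0.58), and UHRF1 (log2 -0.57), CCNE2 (log2 -0.49) and ORC1 (log2 -0.42) fell as well. Of 33 mitosis genes, 12 were lower and 4 higher, also adjusted over the list alone (camera adjusted p = 3.4e-04, and adjusted p = 0.116 with an estimated correlation). MKI67 (log2 -0.34) and CDC20 (log2 -0.29) were among those that fell, and PTTG1 (log2 0.39) and CDC25C (log2 0.31) among those that rose. After median-of-ratios scaling, 21 mitosis genes were lower and 2 higher. Of 25 cholesterol synthesis genes, 8 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.247 with an estimated correlation), with INSIG1 (log2 -0.58) lower and TM7SF2 (log2 0.57) higher. The count of lower genes in this list was 5 without control replicate 1 and 17 after median-of-ratios scaling, and that of higher genes 1 without control replicate 1 or wild type replicate 2. Of 78 ribosomal protein genes, 51 were higher and 0 lower (57 and 0 adjusted over the list alone; camera adjusted p = 4.1e-05, and adjusted p = 0.286 with an estimated correlation), but 13 were higher and 7 lower after median-of-ratios scaling. The leading member was RPS27L (log2 0.76), a ribosomal protein paralog known as a p53 target. Of 77 respiratory chain genes, 58 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 3.3e-06, and adjusted p = 0.116 with an estimated correlation), and 39 higher and 1 lower after median-of-ratios scaling. NDUFA2 (log2 0.47) and ATP5MC1 (log2 0.42) led them.

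The YAP/TEAD target list did not move one way with wild type TEAD4. Of 15 tested members, 6 were higher and 5 lower, also adjusted over the list alone, with 4 and 6 after median-of-ratios scaling and 3 higher without control replicate 2 or without wild type replicate 1 (camera adjusted p = 0.241). The receptor kinase AXL fell from 14.1 FPKM to 6.61 ± 0.231 FPKM (log2 -0.99, adjusted p = 8.7e-06). CYR61 fell from 5.14 ± 0.167 to 3.71 ± 0.183 (log2 -0.38, adjusted p = 0.00121). FJX1 (log2 0.50) and ASAP1 (log2 0.40) rose. CTGF (0.576, 0.215 and 0.408 FPKM in control, wild type and K178R) and ANKRD1 (0.0452, 0.0205 and 0.134 FPKM) did not reach the filter and were not tested. Of 27 Hippo pathway components, 7 were higher and 5 lower (6 and 4 adjusted over the list alone), which turned to 4 and 6 after median-of-ratios scaling, with STK3 (log2 0.43) and FRMD6 (log2 0.38) among those that rose. The count of lower Hippo components was 3 without control replicate 1 or wild type replicate 1. Of 14 Wnt target genes, 7 were higher and 3 lower, also adjusted over the list alone, among them EPHB2 (log2 0.56), EPHB3 (log2 0.51), MYC (log2 0.44) and BMP4. Of 25 epithelial junction and keratin genes, 12 were higher and 6 lower (13 and 6 adjusted over the list alone), against 9 and 10 after median-of-ratios scaling. KRT8 fell from 1298 ± 12.97 to 770 ± 17.7 FPKM and KRT18 from 691 ± 13.6 to 457 ± 10.003, while the junction gene TJP3 rose (log2 1.05). Of 24 AP-1 and immediate early genes, 14 were higher and 3 lower (15 and 3 adjusted over the list alone), led by the MAP kinase phosphatases DUSP4 (log2 1.28) and DUSP6 (log2 1.17), with ATF3 (log2 0.58) and ETV4 (log2 0.49). Of 14 TGF-beta response genes, 7 were higher and 1 lower, also adjusted over the list alone, with ID3 (log2 1.22), BHLHE40 (log2 1.16) and SKIL (log2 0.62) among those that rose. The 1 lower TGF-beta gene became 0 without either control library or wild type replicate 1, and 2 without wild type replicate 2. None of the lists in this paragraph passed camera in the wild type line. fry passed downward for the YAP/TEAD targets (adjusted p = 0.0224). It passed upward for the Wnt (adjusted p = 0.0224), AP-1 (adjusted p = 0.00158) and TGF-beta lists (adjusted p = 4.7e-04). It did not pass for the Hippo (adjusted p = 0.0836) and epithelial lists (adjusted p = 0.81).

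None of the remaining lists passed camera in the wild type line. fry passed upward for the intestinal (adjusted p = 8.4e-04), hypoxia (adjusted p = 0.00644) and histone lists (adjusted p = 0.0216). It also passed upward for the fibroblast and leukocyte markers (adjusted p = 0.0325 for each). It did not pass for the mesenchymal, ATF4 and endothelial lists. Of 30 hypoxia and glycolysis genes, 16 were higher and 6 lower (17 and 6 adjusted over the list alone), with ENO2 (log2 0.69) and MXI1 (log2 0.61) higher and SLC2A3 (log2 -0.56) lower. Of 30 ATF4 and unfolded protein response genes, 11 were higher and 7 lower, also adjusted over the list alone, and 7 and 12 after median-of-ratios scaling. HERPUD1 rose (log2 0.63) and ATF5 fell (log2 -0.70), and the count of higher members was 6 without control replicate 1 or wild type replicate 2. Of 7 mesenchymal genes, 3 were higher and 2 lower, also adjusted over the list alone, with TAGLN lower (log2 -1.18) and FN1 higher (log2 0.36). Of 4 intestinal differentiation genes, 3 were higher, also adjusted over the list alone, among them the carbonic anhydrase CA2 (log2 0.87). Of 20 histone genes, 6 were higher and 2 lower (6 and 1 adjusted over the list alone), and these share near-identical sequence. The 2 lower histone genes became 1 without control replicate 1 or wild type replicate 2. Of 2 fibroblast markers tested, 1 was higher (COL1A1, log2 0.82), and of 2 leukocyte markers 1 was higher (CORO1A, log2 0.69). The 1 endothelial marker tested, ESAM, was not called (log2 0.06). Counts for these markers were the same adjusted over the list alone. In this line the median, the mean and the camera test differed in sign for the YAP/TEAD, Hippo, Wnt, epithelial, mesenchymal, ATF4, leukocyte and endothelial lists. The camera test compares a list with other genes, so it can differ in sign from the list's own values. For the YAP/TEAD (median 0.055, mean -0.0089) and Wnt lists (median 0.148, mean -0.013), the median and the mean themselves differed in sign. The largest changes in these lists were falls, AXL (log2 -0.99) and BMP4 (log2 -2.84).

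With TEAD4 K178R, 1342 genes were higher and 1268 lower than in control. FHL1 had the largest rise, from 1.65 ± 0.0537 to 27.3 ± 0.0934 FPKM (log2 3.41, SE 0.04, adjusted p = 4.3e-08). SYTL2 (log2 2.31), BAMBI (log2 2.21) and GLRX (log2 1.77) followed. The scaffold protein gene NEDD9 went from 0.00372 ± 0.00526 to 2.40 ± 0.132 FPKM (log2 1.76). RGS2, a regulator of G protein signalling, went from 17.6 ± 0.302 to 58.7 ± 0.422 FPKM (log2 1.68), and ARSK (log2 1.65), KRTAP3-1 (log2 1.72) and KRTAP2-3 (log2 1.70) rose as well. BMP4 fell from 79.4 ± 0.193 to 11.4 ± 1.03 FPKM (log2 -2.70, SE 0.07, adjusted p = 1.1e-06) and CAV1 from 127 ± 3.48 to 38.3 ± 0.615 (log2 -1.71). MTUS1 (log2 -2.17), the phosphodiesterase PDE4B (log2 -2.08), KRT13 (log2 -1.75), PKIB (log2 -1.68), ADIRF (log2 -1.58), the semaphorin SEMA3C (log2 -1.58) and the vitamin D hydroxylase CYP24A1 (log2 -1.52) fell too, and U2AF1 (log2 -3.13) is uncertain here as well. The counts rest on small changes. They were 736 higher and 635 lower without control replicate 1, 732 and 664 without control replicate 2, 798 and 734 without K178R replicate 1, 738 and 731 without K178R replicate 2, and 658 and 577 with the control libraries averaged. At an absolute log2 change of at least 1, 38 genes were higher and 26 lower.

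The YAP/TEAD target list rose with K178R, with 9 of 15 members higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.00268, and adjusted p = 0.226 with an estimated correlation). The coagulation initiator F3 went from 27.6 ± 0.913 to 61.0 ± 2.76 FPKM (log2 1.12, SE 0.04, adjusted p = 5e-06), and DOCK5 (log2 0.85) and CRIM1 (log2 0.76) rose, while AXL (log2 -0.77) and CYR61 (log2 -0.33) fell. Of the p53 targets, 14 of 25 were lower and 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 2e-05, and adjusted p = 0.15 with an estimated correlation). CDKN1A fell from 50.9 ± 0.200 to 30.7 ± 0.1198 FPKM (log2 -0.71, adjusted p = 3.9e-06), PLK2 (log2 -1.26) and the apoptosis gene BBC3 (log2 -0.49) fell, and FAS rose (log2 0.52). The count of lower p53 targets was 8 without control replicate 2, 9 without K178R replicate 1 and 10 without either of the others of those lines. Of 33 mitosis genes, 21 were lower and 0 higher (22 and 0 adjusted over the list alone; camera adjusted p = 1.3e-09, and adjusted p = 0.112 with an estimated correlation). Among them were KIF20A (log2 -0.44), CDC20 (log2 -0.40), NEK2 (log2 -0.37) and HMMR (log2 -0.34). That count was 13 without control replicate 1, 11 without control replicate 2, 15 without K178R replicate 1 and 13 without K178R replicate 2. Of 78 ribosomal protein genes, 47 were lower and 0 higher (52 and 0 adjusted over the list alone; camera adjusted p = 2.2e-16, and adjusted p = 0.153 with an estimated correlation). RPS27L (log2 -0.28) and RPS21 (log2 -0.21) led them, and the count was 17 without control replicate 1, 23 without control replicate 2, 21 without K178R replicate 1 and 23 without K178R replicate 2.

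Of 24 AP-1 and immediate early genes, 10 were higher and 4 lower with K178R (12 and 4 adjusted over the list alone; camera adjusted p = 0.00485, and adjusted p = 0.36 with an estimated correlation). DUSP6 (log2 1.55), EGR1 (log2 1.02), EGR3 (log2 0.51) and DUSP4 (log2 0.44) led them. The 4 lower AP-1 genes became 2 without control replicate 1 or K178R replicate 1. Of 4 intestinal differentiation genes, 3 were higher, also adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.29 with an estimated correlation), namely KRT20 (log2 0.89), CA2 (log2 0.65) and MUC13 (log2 0.62). Of 32 DNA replication genes, 9 were lower and 0 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.442 with an estimated correlation). MCM5 (log2 -0.27) and TK1 (log2 -0.25) fell most, and that count was 4 without replicate 1 of control or replicate 2 of K178R and 3 without either of the others. Of 25 cholesterol synthesis genes, 8 were lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.438 with an estimated correlation). TM7SF2 (log2 -0.45) and INSIG1 (log2 -0.38) were lower and HMGCS1 (log2 0.27) higher, and 5 were lower without control replicate 2. The 2 higher members became 1 without any 1 of the control or K178R libraries. The remaining lists did not pass camera. Higher and lower members numbered 4 and 3 of 16 NF-kB genes, with ICAM1 (log2 0.87) and TNFAIP3 (log2 0.60) higher. For the interferon response they numbered 4 and 5 of 28, with SAMD9 (log2 -0.60) lower, and 4 and 6 of 14 Wnt targets, with DKK1 (log2 0.85) higher and SOX9 (log2 -0.65) lower. They numbered 8 and 4 of 25 epithelial genes, with OCLN (log2 0.56) higher and KRT7 (log2 -0.84) lower, and 4 and 3 of 27 Hippo components. Mesenchymal genes had 1 and 1 of 7, with FN1 (log2 0.80) higher, and there were 5 and 2 of 14 TGF-beta response genes. They numbered 7 and 9 of 30 hypoxia and glycolysis genes, with SLC2A1 (log2 0.67) higher, 8 and 2 of 30 ATF4 genes, with SLC7A11 (log2 0.49) higher, 3 and 6 of 77 respiratory chain genes, and 0 and 1 of 20 histone genes. Of the marker lists, 0 of 2 fibroblast, 1 higher and 1 lower of 2 leukocyte (CD68, log2 -0.95) and the 1 endothelial marker ESAM (log2 -0.32) were called, and the call of ESAM ended without any 1 of the control or K178R libraries. That of CORO1A (log2 0.35) ended without either control library or K178R replicate 2, and with the replicate number as a block. Adjusted over the list alone, these counts changed by at most 1 per direction. Several changed when 1 library was left out, which leaves 1 library in its group. The 2 lower TGF-beta response genes became 0 without any 1 of the control or K178R libraries. Without control replicate 1, higher counts were 2 for Hippo components and 5 for epithelial genes, and lower counts were 3 for interferon, 3 for hypoxia and 1 for respiratory chain genes. Without control replicate 2, higher counts were 2 for Hippo, 2 for Wnt, 2 for interferon, 4 for hypoxia and 1 for respiratory chain genes, and lower counts 1 for NF-kB and 3 for hypoxia genes. Without K178R replicate 1, higher counts were 1 for Hippo, 5 for epithelial, 3 for TGF-beta, 2 for interferon, 4 for hypoxia and 1 for respiratory chain genes, and lower counts 1 for NF-kB, 5 for hypoxia and 2 for respiratory chain genes. Without K178R replicate 2, higher counts were 2 for Hippo, 5 for epithelial and 2 for NF-kB genes, and lower counts 4 for hypoxia and 3 for respiratory chain genes.

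Many genes differed from control in the same direction in the wild type TEAD4 and K178R lines. Both were compared with the same control line. A difference of that line or its culture cannot be told apart from an effect of TEAD4. Against control, 1057 genes were higher in both lines and 515 lower in both, beside 505 and 155 for independent lists and 0.02 and 0.04 in simulations of unchanged groups with shared controls. Genes called in opposite directions numbered 253, beside 642 for independent lists and 0 in the simulations. With no gene changed, the simulations call almost none, so their low counts were fixed in advance. They do not measure the overlap that shared controls add among changed genes. Across the 11445 genes, which are not independent, Pearson's r of both log2 changes was 0.58 beside 0.50 in the simulations, and their covariance was 0.0335 beside 0.00221. With each line set against a control library of its own, 821 or 796 genes had the same direction (beside 262 and 272 for independent lists) and 99 or 124 opposite directions, depending on which line took which library, and r was 0.52 or 0.49. The simulated r of 0.50 comes from the shared control libraries alone. It is no reference for r with separate control libraries, which was not simulated. The control libraries are not known to be separate cultures. Of the 67 genes that rose by at least 1 on the log2 scale with wild type TEAD4, 48 were also called higher with K178R, 1 was lower and 18 were not called. Of the 22 that fell as much, 20 were also lower with K178R. All 38 genes that rose and all 26 that fell by at least 1 with K178R were called in the same direction with wild type TEAD4. The count of genes called in the same direction in both comparisons fell from 1572 to 877 without control replicate 1, 863 without control replicate 2, 1003 without K178R replicate 1 and 978 without K178R replicate 2.

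**Figure D2:**
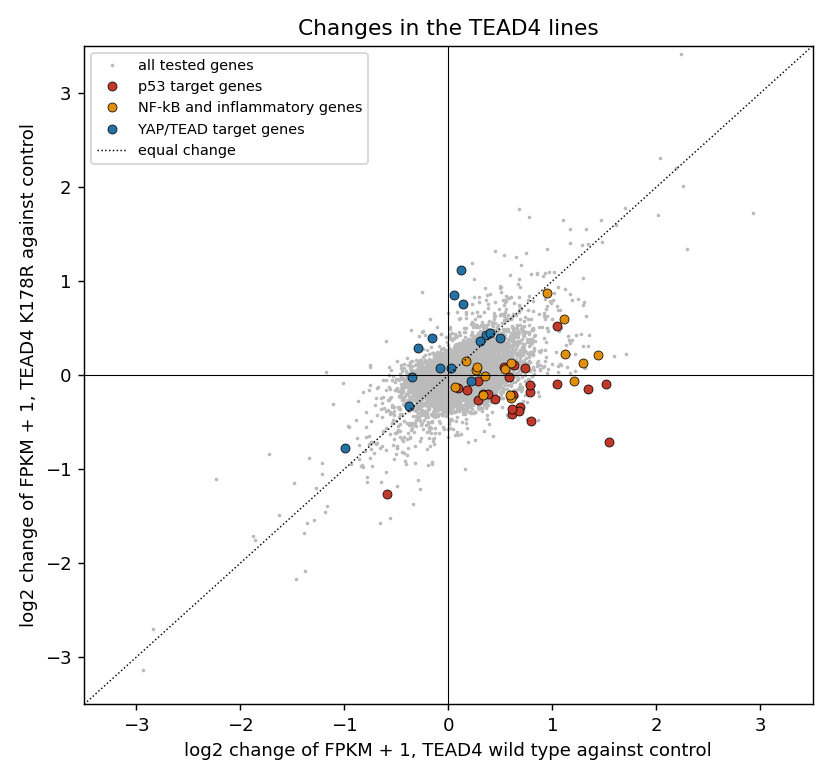
Log2 change of FPKM + 1 against control for each of 11445 tested genes, wild type TEAD4 on the horizontal and K178R on the vertical axis, with the tested p53, NF-kB and YAP/TEAD list members coloured. Of the 25 p53 targets, 23 were called higher with wild type TEAD4 and 14 lower with K178R, and the dotted line marks equal change.

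The direct comparison sets the K178R line against the wild type line. An effect of the mutation cannot be told apart from other differences between these lines or their cultures. The lines also differed in TEAD4 RNA (71.8 FPKM in K178R and 85.4 in wild type). The p53 targets were lower in K178R, 25 of 25, also adjusted over the list alone and under both other scalings (camera adjusted p = 7.4e-14, and adjusted p = 0.0707 with an estimated correlation). The mean FPKM of CDKN1A in wild type was 4.90 times that in K178R (on the log2(FPKM + 1) scale -2.26, SE 0.03, adjusted p = 2.7e-08), and GDF15 (log2 -1.61), TP53INP1 (log2 -1.49) and BBC3 (log2 -1.28) were lower as well. The NF-kB list had 12 of 16 members lower and 0 higher, also adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.0844 with an estimated correlation). BIRC3 (log2 -1.27), RELB (log2 -1.23) and CXCL1 (log2 -1.17) differed most. Of 28 interferon response genes, 19 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 9.8e-05, and adjusted p = 0.0844 with an estimated correlation). PSMB9 (log2 -1.48), TAP1 (log2 -0.93) and IFI35 (log2 -0.81) were lower. The 1 higher interferon gene became 0 without any 1 of the wild type or K178R libraries. Outside these lists, the decoy receptor gene TNFRSF10C (log2 -1.34), the serpin gene SERPINB5 (log2 -1.21), the autophagy receptor gene OPTN (log2 -1.17) and KRTAP3-1 (log2 -1.20) were also among the 10 largest falls. CDKN1A, TNFRSF10C, BBC3, SERPINB5 and KRTAP3-1 were called in all 3 comparisons.

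Higher in K178R than in wild type was TAGLN, an actin-binding protein of contractile cells, at 3.18 ± 0.302 against 0.799 ± 0.0279 FPKM (log2 1.22, SE 0.07, adjusted p = 4.5e-05). FHL1 (log2 1.18), KRT20 (log2 1.14), ANXA3 (log2 1.12), NEDD9 (log2 1.08), F3 (log2 0.99), KRT18 (log2 0.96), RGS2 (log2 0.91), KRT7 (log2 0.89) and SEMA3A (log2 0.87) were higher as well. The YAP/TEAD target list had 8 of 15 members higher and 1 lower, also adjusted over the list alone and under both other scalings (camera adjusted p = 9.4e-07, and adjusted p = 0.0844 with an estimated correlation). DOCK5 (log2 0.80), CRIM1 (log2 0.62) and MYOF (log2 0.58) were higher beside F3, and without wild type replicate 2 the lower members were 2. Of 32 DNA replication genes, 21 were higher and 3 lower (23 and 4 adjusted over the list alone; camera adjusted p = 2.1e-11, and adjusted p = 0.124 with an estimated correlation). GINS2 (log2 0.45), UHRF1 (log2 0.44), CDC6 (log2 0.40) and MCM10 (log2 0.38) were higher. The 3 lower members became 0 after median-of-ratios scaling. Of 78 ribosomal protein genes, 74 were lower and 0 higher (75 and 0 adjusted over the list alone; camera adjusted p = 8.3e-16, and adjusted p = 0.0844 with an estimated correlation), and 59 and 0 after median-of-ratios scaling. RPS27L (log2 -1.04) and RPL3 (log2 -0.40) led them. Of 77 respiratory chain genes, 64 were lower and 0 higher (70 and 0 adjusted over the list alone; camera adjusted p = 3e-09, and adjusted p = 0.0844 with an estimated correlation), and 42 and 1 after median-of-ratios scaling. Over all genes, 1187 were higher and 3952 lower in K178R than in wild type, against 2244 and 2535 after median-of-ratios scaling and 1951 and 2789 after upper-quartile scaling. At an absolute log2 change of at least 1, 5 were higher and 28 lower.

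Of 30 ATF4 and unfolded protein response genes, 9 were higher and 7 lower in K178R than in wild type (10 and 8 adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.116 with an estimated correlation), and 16 and 4 after median-of-ratios scaling. SLC7A5 (log2 0.51) and SLC7A11 (log2 0.47) were higher. Of 25 epithelial genes, 7 were higher and 7 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.0412, and adjusted p = 0.186 with an estimated correlation), and 11 and 7 after median-of-ratios scaling. KRT8 (log2 0.84) was higher and TJP3 (log2 -0.96) lower. Lists that did not pass camera moved with the scaling in several cases. Higher and lower members numbered 1 and 17 of 33 mitosis genes, against 7 and 8 after median-of-ratios scaling, 2 and 5 of 27 Hippo components, against 7 and 4, and 1 and 6 of 14 Wnt targets, against 4 and 3. The AP-1 list turned too, with 6 and 7 of 24 genes, against 9 and 6 under that scaling. The cholesterol list had 5 and 4 of 25, against 11 and 3. Without wild type replicate 1, 3 mitosis, 2 Wnt and 2 histone genes were higher, and without K178R replicate 1, 2 intestinal and 1 TGF-beta genes were. The 2 higher Hippo components became 1 without replicate 1 of either line, and the AP-1 list had 3 higher members without wild type replicate 2. The cholesterol list had 3 higher without wild type replicate 2, 2 higher without K178R replicate 2 and 2 lower without K178R replicate 1. SOX9 (log2 -1.07), RNF43 (log2 -0.69) and DUSP4 (log2 -0.84) were lower and EGR1 (log2 0.77) was higher. They numbered 0 and 6 of 14 TGF-beta response genes, with ID3 (log2 -0.80) and ID1 (log2 -0.61) lower, and 5 and 15 of 30 hypoxia and glycolysis genes, with NDRG1 (log2 -0.60) lower. After median-of-ratios scaling the former had 2 and 5 and the latter 9 and 12. Smaller lists had 3 and 3 of 7 mesenchymal genes, 1 and 2 of 4 intestinal genes, 0 and 7 of 20 histone genes, 0 and 1 of 2 fibroblast markers, 0 and 2 of 2 leukocyte markers, and 0 and 1 of 1 endothelial marker. The call of the leukocyte marker CORO1A (log2 -0.34) ended after median-of-ratios scaling and without replicate 1 of either line. Adjusted over the list alone, these counts changed by at most 1 per direction. The median, the mean and the test differed in sign for the Hippo, mesenchymal, intestinal, AP-1 and cholesterol lists here, and for the hypoxia list in K178R against control.

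**Figure D3:**
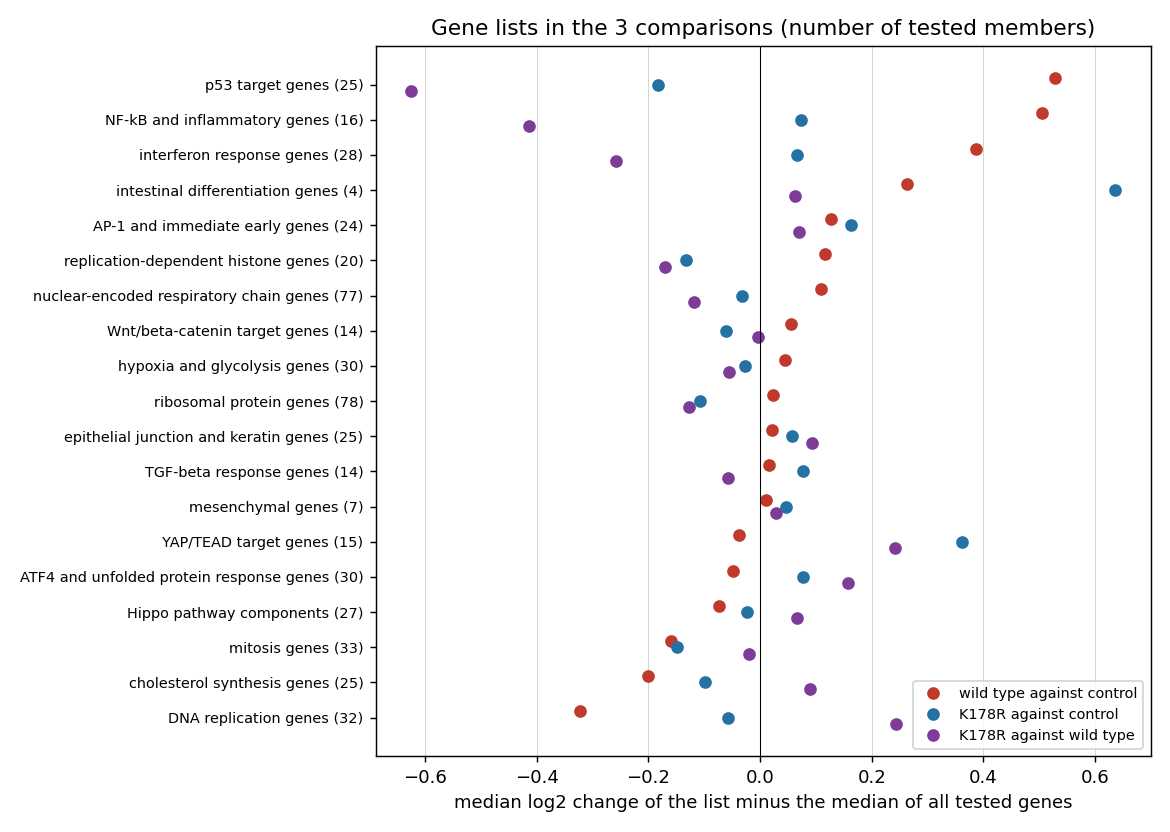
Median log2 change of each list with at least 4 tested members, minus the median of all tested genes, in the 3 comparisons, with the number of tested members in brackets. The p53 targets lie at 0.53 for wild type against control, -0.18 for K178R against control and -0.62 for K178R against wild type.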

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

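Tests at a threshold of 1.5-fold, with the control libraries averaged, with each line against a control library of its own and with a GC and length trend removed were chosen after the data were seen. TEAD4 kept its direction and its calls under all settings run except the fold thresholds, where its difference between K178R and wild type is too small to be called. With median-of-ratios scaling, wild type TEAD4 against control gave 2865 genes higher and 2498 lower, and K178R against wild type 2244 and 2535; this scaling centres the ratios, so a near-even split follows from its construction. With upper-quartile scaling, 2162 were lower in the former and 1951 higher in the latter. At an absolute log2 change of at least 1, the counts were 67 higher and 22 lower for wild type against control, 38 and 26 for K178R against control, 5 and 28 for K178R against wild type, and 35 in the same direction in both comparisons with control. At 1.5-fold they were 420 and 81, 143 and 109, 33 and 270, and 133; a fold threshold lowers counts by construction. With the control libraries averaged, K178R against control gave 658 higher and 577 lower, and 790 genes had the same direction in both, with 1 library fewer. With each line against a control library of its own that number was 821 or 796, from 1 control library per comparison. Leaving out each library in turn, which in the group left with 1 assumes that it varies like the others, gave 732 to 1266 higher and 635 to 1229 lower genes for K178R against control, and 863 to 1345 for the shared direction. These counts fell by a similar amount whichever control or K178R library was left out. A group left with 1 library gives larger standard errors, so fewer small changes pass. The falls therefore do not single out 1 library. With the replicate number as a replicate block, wild type TEAD4 against control gave 4178 higher and 1334 lower genes, and K178R against control 1210 and 1154. Removing the GC and length trend left 4256 higher and 1427 lower with wild type TEAD4. Without the filter, 4116 and 1279 of 15960 genes were called. The count-based alternatives that had been set were not run, since the files hold FPKM. Relative depth is known and absolute depth is not, so no count limit can be given for genes listed at 0.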

Other observations

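The gene groups and MYL9 in the first paragraph were chosen after the values were seen. So were the values given for U2AF1 and the tests of the p53 pattern. The tests of the split of calls were set before their results. Among them, a test of background replaced one on GC content and length, and its explanation was narrowed after its value was seen. Of 7 gene groups looked at later, one was HOXB genes, transcription factors of body patterning. Of 9 tested, 9 were higher with wild type TEAD4 (8 after either other scaling) and 8 with K178R, with HOXB8 at 6.76, 20.6 and 19.6 FPKM in control, wild type and K178R, and HOXB9 at 6.22, 17.1 and 20.2. HOXA genes were higher in 3 of 8 and HOXC genes in 2 of 6 with wild type TEAD4, and HOXD genes in 0 of 2. HOXB genes lie side by side, and without a stated use of strand their reads and those of antisense transcripts cannot be separated. Of 6 tested ligands of the EGF receptor, 6 were higher in both TEAD4 lines under each scaling, with AREG at 150 FPKM in control, 223 in wild type and 195 in K178R and EREG at 143, 170 and 191. Of 3 collagen IV genes, 3 were higher with wild type TEAD4 and 2 with K178R. Of 20 actin, tubulin and tropomyosin genes, 9 were lower in each TEAD4 line and 6 and 2 higher. ACTB stood at 1479 FPKM in control, 927 in wild type and 1356 in K178R, and MYL9 at 44.7, 20.2 and 35.9.

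Target genes of p53 were higher with wild type TEAD4 and lower with K178R. Scaling of the libraries is argued against, as 22 of 25 were still higher after median-of-ratios scaling. A response in proportion to TEAD4 RNA that is the same for both proteins would raise the list in both lines. It is argued against as the sole cause only. The fall with K178R was already part of the pattern when this test was set, so its outcome was known in advance. Such a response masked by a difference between the lines is not excluded. The median log2 change with K178R was -0.18 (95% bootstrap interval over genes -0.26 to -0.10) while TEAD4 rose in both lines. TEAD4 FPKM in wild type was 1.19 times that in K178R. The interval treats the genes as independent and does not measure the spread between lines. A response to the level of wild type TEAD4 alone was not tested, since the K178R line also carries the mutation. A difference between the lines or their cultures apart from TEAD4, such as stress or density, stays open and may be the source. The libraries of the wild type group differed by 1.82% beyond counting noise, but they are not known to be separate lines or cultures, so this cannot be told apart from an effect of TEAD4 or the mutation.

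More genes were higher than lower with wild type TEAD4. A uniform difference in scale is argued against as the whole cause, since the median log2 ratio of the lowest quartile of genes by mean FPKM exceeded that of the highest by 0.19 (95% interval 0.17 to 0.21). Whether the most abundant genes losing reads account for part of it is not settled. With each library scaled by its total without the 100 genes of most reads, the median of all genes was 0.057 instead of 0.09. The main fit had no added scaling, so this difference mixes the scaling with leaving out those genes. They held 20.9% of estimated reads in control, 20.2% in wild type and 20.1% in K178R. The median of all genes was 0.002 for K178R against control, so a like loss came without that shift there. No value says which scale is right. A uniform background such as genomic DNA is argued against as the whole cause. Genes of 0.05 to 0.3 FPKM gained 12.9% (11.2% to 15.3%) of the rise of the lowest quartile of expressed genes. A background as part of the cause stays open. Genes listed at 0 numbered 5319 and 5310 in the wild type libraries, at relative depths of 0.933 and 0.920, and 5640 and 5623 in control. The explanation was narrowed to an even background after the 12.9% was seen, and unspliced RNA stays open.

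U2AF1 was lower in both TEAD4 lines, but its control libraries read 19.6 and 5.71 FPKM, 3.43-fold apart. U2AF1 and its near-identical copy U2AF1L5 summed to 20.4 and 6.49 FPKM there, so a shift of reads between both copies alone does not give this gap. CBS and CBSL, another such pair, are listed at 0 in all libraries. No other explanation was examined for this gene, and its change is left as uncertain.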
